A study of Mus musculus with 15 samples.

How the data were processed

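Periprostatic white fat of 15 male mice was profiled by RNA sequencing, with 5 mice in each of the groups LFD, HFD placebo and HFD estradiol. Per the labels' protocols, total RNA with an integrity number above 7 was depleted of ribosomal RNA and made into stranded libraries for Illumina sequencing. Reads were aligned to mouse genome mm10 with STAR and quantified with Cufflinks, per the submitters' processing notes, which give no versions. How reads shared between near-identical genes were assigned, and which annotation was used, is not given in the sources used here. The authors deposited 1 file per library with FPKM, fragments per kilobase of transcript relative to all fragments of the library, by gene symbol. Of the symbols listed, 5115 were at 0 in all libraries and 18880 were above 0 in at least 1. The members of the list of mitochondrially encoded genes were not among the symbols, so that list gave no result. Only 3 genes, Rnu11, Snora44 and Snora7a, had a median FPKM above 5 and a 0 in some library.

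Groups and replicate numbers were taken from the labels. The numbers 1 to 5 name different animals, and libraries were treated as unpaired. Sequencing lanes were read from the names of the deposited files: 8 libraries lay on lane 5 and 7 on lane 6. The LFD group had no pellet implanted, so diet and pellet placement change together between LFD and the other groups. No pair of libraries was identical, and correlations of log2 values within groups ran from 0.927 to 0.979.

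The sum of FPKM per library ran from 34449 to 105910, so each library was scaled by a median-of-ratios factor computed over the 5874 genes above 0 in every library with a mean FPKM of at least 1. The factors ran from 0.309 to 2.08. Genes with a scaled FPKM of at least 1 in at least 5 libraries were tested, 5615 in all. Values were transformed as log2(scaled FPKM + 1). Differences between groups were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, on all 15 libraries with the group as the only factor. The adjusted p is that of Benjamini and Hochberg over the tested genes within each comparison, with 0.05 as the threshold. The 3 comparisons were HFD placebo minus LFD, HFD estradiol minus HFD placebo, and HFD estradiol minus LFD.

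Before the data were examined, 44 gene lists with 942 members were written from general knowledge of adipose tissue, steroid hormones, immune cells and neighbouring tissues. Of the members 918 were found in the files, 3 of them by an older symbol, which included Emr1 for Adgre1. Genes can belong to more than 1 list, and the 918 are 887 different genes. The 35 lists with at least 3 tested members were tested with camera, from limma, which compares a list with the other genes, at its preset correlation of 0.01 between genes and adjusted over the lists. They were also tested with camera at a correlation estimated from the data, under which no list passed in any comparison, and with fry, which asks whether a list moves one way on balance without comparing it with other genes. Fry called 21, 14 and 4 lists in the 3 comparisons. For each list the calls of its members are also given with the correction made over its own members, described as adjusted over the list alone.

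The genes named in the text were chosen by a rule written before the data were examined. For each comparison it takes the 10 largest rises and the 10 largest falls among called genes with a mean scaled FPKM of at least 2 over both groups and with groups that do not overlap, leaving out predicted genes and small RNAs. It adds up to 4 members with the smallest adjusted p of each list that passed, and genes of prior interest, among them Esr1, Pgr, Greb1, Lep, Adipoq, Fasn, Scd1, Ucp1, Ccl2, Trem2, Mest, Cyp19a1 and Pbsn. Genes outside the rule are given as chosen after their values were seen. Positions are from the GENCODE vM21 annotation of GRCm38, the assembly of mm10, in which 144 of 145 named genes were located.

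Genes below the tested level, together with Cd79a and Cd79b, which limma also tested, were compared by an exact two-sided permutation test. It took the difference in mean scaled FPKM and was adjusted over 24 tests. These included tests of Cd79a, Cd79b, Top2a and Il7r, chosen after their values were seen. With 5 mice in each group the smallest p that the exact test can give is 0.0079.

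No counts of reads were used here. Depth was estimated for each library from the spacing of its lowest FPKM values in 1636 genes with a single transcript longer than 2000 bases, with 200 bases taken off each length. Between 54.2% and 66.0% of low values lay within 2% of a whole multiple, up to 4, of the estimated unit. A scaled FPKM of 1 in a 2 kb transcript was so estimated at 20.7 to 221 fragments over the libraries. These are estimates and give no interval for single values.

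The procedure was run on simulated data made from the real means and spreads with known changes. Of genes changed by 1 on the log2 scale it recovered 91.5% for HFD placebo against LFD, simulated over 5120 tested genes, 91.8% for HFD estradiol against HFD placebo over 5512 genes, and 87.8% for HFD estradiol against LFD over 5331 genes. For a change of 0.5 these shares were 61.4%, 56.3% and 53.1%. These changes were made before the 1 of log2(scaled FPKM + 1) was added, and were estimated smaller. In the same order, a change of 1 had a median estimate of 0.65, 0.67 and 0.68. A change of 0.5 had one of 0.36, 0.33 and 0.31. The shares thus do not hold for reported log2 fold changes of 1 and 0.5. False calls were 10 of 193, 5 of 193 and 7 of 184. Few genes were changed, as many up as down beside the raised mature adipocyte list, and genes were drawn independently of each other. In the data 43.3% of tested genes were called for HFD placebo against LFD. The simulation thus does not test the scaling where many genes change, nor the list tests where genes move together.

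The shared use of the placebo libraries makes the first 2 comparisons move against each other by construction. The share of diet-changed genes with the opposite sign was therefore set against 100 simulations with no group effect. Each simulation took as many genes as were called with diet, those of smallest p, whether or not they passed. The share was also recomputed with different placebo libraries in each comparison, in 20 ways.

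Alternatives tried were FPKM as deposited, FPKM rescaled to a constant sum per library, quantile normalization, other pseudocounts, no filter and a stricter filter on low values, array weights, moderation without the robust option, fits of only the 2 groups compared, leaving out genes of the other-tissue lists, lane as a term, the replicate number as a block, leaving out each library in turn, and the other list tests. Fits within each lane, and fits without libraries that held brown fat, prostate or muscle transcripts, were added after the data were seen. Versions used were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Figures were drawn from the same tables.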

Results

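RNA from the periprostatic white fat of 15 male C57BL/6J mice was sequenced at 26 weeks of age. Periprostatic fat is the adipose tissue that surrounds the prostate. The mice formed 3 groups of 5 animals. The LFD group ate a low-fat diet with 10 kcal% fat and carried no pellet. The HFD placebo group ate a high-fat diet with 60 kcal% fat and carried a placebo pellet, and the HFD estradiol group ate the same high-fat diet and carried a pellet with 0.25 mg of estradiol, an estrogen, released over 60 days. Diets began at 6 weeks of age, pellets were placed after 12 weeks of diet, and tissue was taken 8 weeks later. Each library was deposited as FPKM, the fragments per kilobase of transcript relative to all fragments of the library, by gene symbol. The replicate numbers name different animals, so the spread between replicates is the spread between mice.

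The sum of FPKM per library ran from 34449 to 38755 in LFD, from 34544 to 105910 in HFD placebo and from 37561 to 60725 in HFD estradiol. The 2 highest sums, 105910 and 99489, were those of placebo 4 and 5 on sequencing lane 6, and the 3 placebo libraries on lane 5 ran from 34544 to 55053. The small RNA entry Mir6236, which lies within the ribosomal RNA repeat, took between 10.2% and 53.1% of that sum. Between 13891 and 16648 genes per library had a value above 0. Read counts were not used here, and depth was estimated from the steps between the lowest values of each library. The lowest level tested, a scaled FPKM of 1, corresponds in a 2 kb transcript to an estimated 20.7 to 40.2 fragments in LFD, 34.9 to 221 in HFD placebo and 36.8 to 96.2 in HFD estradiol. Values below are FPKM scaled by 1 factor per library, given as mean ± SD over 5 mice, and log2 fold changes are on the log2(scaled FPKM + 1) scale, which understates the change of low genes. The files' names place all LFD libraries on sequencing lane 5, all HFD estradiol libraries on lane 6, and the HFD placebo libraries on both, 3 on lane 5 and 2 on lane 6. The first principal component carried 53.8% of the variance. It ran from -23.2 to -10.7 in LFD, from -9.33 to 2.47 in HFD estradiol and from 9.67 to 26.8 in HFD placebo, so that the placebo libraries of both lanes lay on one side.

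**Figure D1:**
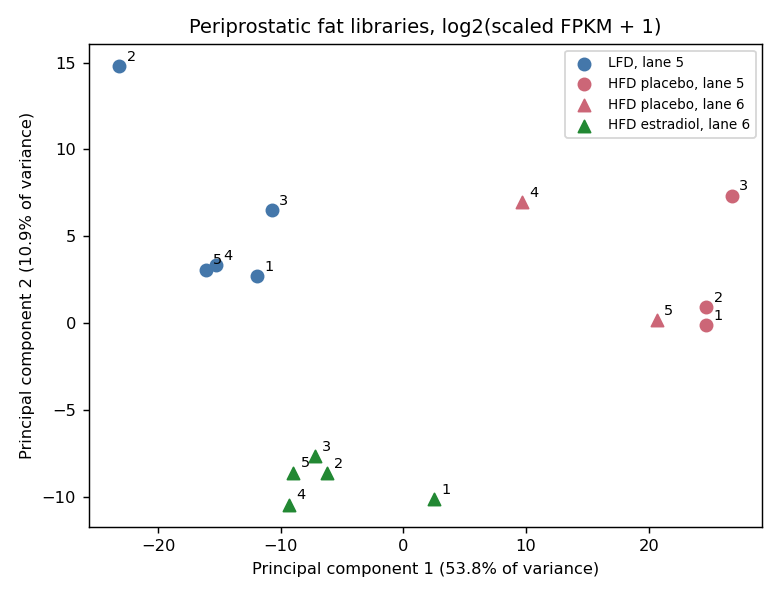
Principal components 1 and 2 of log2(scaled FPKM + 1) over the 5615 tested genes, 1 point per mouse, with colour for group, shape for sequencing lane and the replicate number beside each point. The HFD placebo libraries lie between 9.67 and 26.8 on component 1, to the right of the 10 others, and the HFD estradiol libraries lie between -10.5 and -7.69 on component 2, below the 10 others.

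The first comparison, HFD placebo against LFD, asks how diet-induced obesity changes this fat depot; diet and pellet placement differ together in it. The 10 largest rises and 10 largest falls named for each comparison were taken only from called genes whose groups do not overlap. Macrophage genes were among the largest rises. Gpnmb, a lysosomal glycoprotein of lipid-loaded macrophages (GRCm38 chromosome 6, 49036546 to 49070929, protein coding), averaged 25.3 ± 11 in HFD placebo and 0.432 ± 0.169 in LFD, a log2 fold change of 4.07 (limma adjusted p = 1.4e-06). Trem2, a lipid-sensing receptor of macrophages, averaged 8.23 ± 2.54 against 0.206 ± 0.134, and Cd68, a lysosomal macrophage marker, 31.6 ± 10.2 against 2.73 ± 0.658 (limma adjusted p = 7.8e-07 and 4.3e-07). The metalloelastase Mmp12, the galectin Lgals3, the protease Ctss, the proton pump subunit Atp6v0d2, the signalling adaptor Tyrobp and the ubiquitin-like Ubd were also among the 10 genes with the largest rises, with log2 fold changes from 2.70 for Tyrobp to 3.78 for Mmp12. The other was Mest, a gene linked to adipocyte enlargement, at 22.3 ± 4.23 against 2.91 ± 2.80 (log2 fold change 2.83). Emr1, the older symbol of the macrophage marker Adgre1, averaged 13.7 ± 12.5 against 1.55 ± 0.581 (log2 fold change 2.26, limma adjusted p = 7.8e-05). Placebo 3 stood at 35.9 for Emr1, where the other placebo libraries ran from 5.58 to 9.72, and without it the log2 fold change was 1.85 (limma adjusted p = 8.9e-06).

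Lists of macrophage, cytokine, antigen presentation and matrix genes were higher as well. Of 17 tested genes of lipid-associated macrophages, 15 rose and none fell, with a median log2 fold change of 2.04 (camera adjusted p = 8.7e-11, and adjusted p = 0.275 with an estimated correlation); 16 rose when adjusted over the list alone. Of 21 macrophage genes, 18 rose, with a median of 1.61 (camera adjusted p = 6.1e-09, and adjusted p = 0.306 with an estimated correlation), and adjusted over the list alone 18 rose and 1 fell. Of 10 inflammatory cytokine and chemokine genes 8 rose, a count that was also 8 adjusted over the list alone. The median was 1.10, with camera adjusted p = 1.4e-04 and adjusted p = 0.275 with an estimated correlation. Among them Ccl2, a chemokine that attracts monocytes, averaged 4.21 ± 1.47 against 0.543 ± 0.459. All 7 tested genes of MHC class II antigen presentation rose, by either adjustment, including adjusted over the list alone. Their median log2 fold change was 1.10, with camera adjusted p = 5.6e-05 and adjusted p = 0.306 with an estimated correlation. Among the 7 are 5 H2 genes, whose close relatives make their values uncertain. Of 29 genes of extracellular matrix and fibrosis, 24 rose, and 24 adjusted over the list alone. The list median was 0.83, with camera adjusted p = 1.3e-09 and adjusted p = 0.306 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, averaged 2.28 ± 0.838 against 0.119 ± 0.0955, the collagen gene Col6a3 7.35 ± 1.61 against 2.32 ± 0.328, and Col1a1 7.71 ± 3.01 against 2.72 ± 0.672. Replication-dependent histone genes rose in 8 of 13 cases, 11 adjusted over the list alone (median 0.64, camera adjusted p = 9.9e-05, and adjusted p = 0.306 with an estimated correlation), and cytosolic ribosomal protein genes in 14 of 39, 13 adjusted over the list alone. Without placebo 2 the histone median was 0.41. The median of the ribosomal list was 0.24, with camera adjusted p = 3.6e-04 and adjusted p = 0.670 with an estimated correlation. Histone and ribosomal protein genes have near-identical copies, so their values are uncertain. The following lists of other cells did not pass camera. Of 18 endothelial genes none rose and 4 fell, 2 adjusted over the list alone (camera adjusted p = 0.299). Of 12 adipose progenitor genes 5 rose and 1 fell, with the same counts adjusted over the list alone, and of 9 smooth muscle genes 3 rose and 1 fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.522 for both). Of 4 B and plasma cell genes 3 fell, and 3 adjusted over the list alone, and of 6 genes of neutrophils, mast cells and eosinophils 1 rose, and 1 adjusted over the list alone (camera adjusted p = 0.232 and 0.742). The endothelial median was -0.074, and 0.68 with FPKM as deposited, where the median of all genes shifted by 0.77.

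Adipocyte and lipid synthesis genes were among the largest falls. Cyp2e1, a cytochrome P450 (chromosome 7, 140763739 to 140774987), averaged 8.31 ± 2.46 in HFD placebo and 162 ± 41.1 in LFD, a log2 fold change of -4.12 (limma adjusted p = 2.0e-08). Cfd, the adipocyte-secreted complement factor adipsin (chromosome 10, 79890853 to 79892655), averaged 49.4 ± 19.9 against 711 ± 187 (log2 fold change -3.85, limma adjusted p = 1.1e-07). The lipogenic genes Thrsp, Fasn (fatty acid synthase, chromosome 11, 120805846 to 120824547), Acaca and Acly were among the 10 largest falls, with log2 fold changes of -3.23, -2.54, -2.42 and -2.07. Fasn averaged 17.4 ± 4.12 against 115 ± 60.2, and the stearoyl-CoA desaturase Scd1 371 ± 98.4 against 1203 ± 286 (log2 fold change -1.71, limma adjusted p = 7.8e-06). The others of the 10 were the adipokine Retn, the glutathione transferase Gsta3, the adipocyte adrenergic receptor Adrb3 and the carbonic anhydrase Car3. Acly and Car3 were among the calls lost with FPKM as deposited. Of 18 genes of de novo lipogenesis 17 fell, and 17 adjusted over the list alone. The median was -1.40, with camera adjusted p = 4.7e-09 and adjusted p = 0.306 with an estimated correlation. Of 18 genes of branched chain amino acid catabolism 16 fell, and 17 adjusted over the list alone. Their median log2 fold change was -0.84, with camera adjusted p = 2.3e-09 and adjusted p = 0.306 with an estimated correlation. Of 24 mature adipocyte genes 16 fell and 1, Lep, rose, with the same counts adjusted over the list alone. The list median was -0.66, with camera adjusted p = 1.8e-06 and adjusted p = 0.382 with an estimated correlation. Lep, which encodes leptin (chromosome 6, 29060220 to 29073877), averaged 53.0 ± 7.67 against 23.1 ± 7.10 (log2 fold change 1.2, limma adjusted p = 2.1e-04), and Adipoq, which encodes adiponectin, 80 ± 21.5 against 166 ± 25.9 (log2 fold change -1.07, limma adjusted p = 9.4e-05).

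Genes of energy and insulin handling were lower as well. Of 22 tricarboxylic acid cycle genes 16 fell, and 16 adjusted over the list alone. Their median was -0.49, with camera adjusted p = 9.4e-05 and adjusted p = 0.670 with an estimated correlation. Of 40 nuclear genes of oxidative phosphorylation 16 fell, and 14 adjusted over the list alone. The median was -0.33, with camera adjusted p = 2.4e-04 and adjusted p = 0.708 with an estimated correlation. Of 19 genes of insulin signalling and glucose handling 13 fell and 3 rose, with the same counts adjusted over the list alone. Their median log2 fold change was -0.48, with camera adjusted p = 0.0010 and adjusted p = 0.234 with an estimated correlation. Slc2a4, the insulin-responsive glucose transporter, averaged 1.66 ± 0.506 against 5.53 ± 1.49, and Irs1, an insulin receptor substrate, 0.687 ± 0.107 against 2.07 ± 0.329. The 3 that rose were Akt1, Foxo3 and Ptpn1, named after their values were seen. Ptpn1 encodes a phosphatase that acts on the insulin receptor. Of 8 genes of steroid hormone metabolism 5 fell, and 5 adjusted over the list alone (median -0.36, camera adjusted p = 0.0440, and adjusted p = 0.306 with an estimated correlation); without LFD 2 or without placebo 2, 3 or 4 the list no longer passed, with adjusted p up to 0.0641.

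By limma, 2431 of the 5615 tested genes differed at an adjusted p below 0.05, of which 1197 were higher and 1234 lower in HFD placebo. Of these, 330 changed by more than 1 on the log2 scale, 230 up and 100 down. Of all 5615 tested genes 1547 had groups that did not overlap, where chance gives 0.794% of genes. Directions are relative to the median gene, and 49.2% of the called genes were higher with the factors used. Over the same tested genes it was 99.4% with FPKM as deposited and 91.3% with FPKM rescaled to a constant sum per library. The median of all tested genes itself then lay 0.77 and 0.42 above LFD. As deposited, the medians of the mature adipocyte, tricarboxylic acid cycle, oxidative phosphorylation, branched chain amino acid, insulin and steroid lists were 0.49, 0.54, 0.71, 0.091, 0.28 and 0.40, that is positive but below the shift of all genes, Adipoq stood at 0.077, and de novo lipogenesis at -0.45. These signs rest on placebo 4 and 5: as deposited, the median of all genes lay 0.23 above LFD in the 3 placebo libraries of lane 5 and 1.59 above it in the 2 of lane 6, and in the lane 5 libraries the same 6 lists stood at -0.41, -0.20, -0.057, -0.56, -0.23 and -0.091 and Adipoq at -0.87. Rescaled to a constant sum, oxidative phosphorylation stood at 0.063. Within lane 5, where 3 placebo and 5 LFD libraries can be compared, 1343 of 3463 tested genes differed. Factors and tested genes were set anew from these libraries, so the count and medians are not on the same scale as over all libraries. The lipid-associated macrophage list had a median of 1.40 there and de novo lipogenesis of -1.37. The filter within lane 5 dropped members near 0 in LFD, such as Gpnmb and Trem2, so 1.40 rests on fewer members than the median over all libraries. As deposited, the median of all 17 members in the lane 5 placebo libraries lay 1.90 above that of all genes.

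The second comparison, HFD estradiol against HFD placebo, asks what estradiol does on the high-fat diet. Macrophage genes were among the largest falls. Gpnmb averaged 2.26 ± 2.71 with estradiol and 25.3 ± 11 with placebo, a log2 fold change of -3.16 (limma adjusted p = 2.5e-05). Lgals3 averaged 6.49 ± 3.85 against 42.4 ± 10.6, Cd68 6.12 ± 2.37 against 31.6 ± 10.2, and Trem2 1.23 ± 1.14 against 8.23 ± 2.54, with log2 fold changes of -2.62, -2.18 and -2.11. Estradiol 1 lay above the other estradiol libraries, at 7.09 for Gpnmb, where they ran from 0.668 to 1.34, and at 3.25 for Trem2, where they ran from 0.411 to 0.882; without it the log2 fold changes were -3.53 and -2.35 (limma adjusted p = 1.0e-06 and 8.9e-07). Ubd, Ctss, Atp6v0d2, the membrane protease Adam8, the leukocyte antigen Cd52 and the calcium-binding S100a4 completed the 10 largest falls, with log2 fold changes between -2.50 and -1.99. Mmp12 also fell (log2 fold change -2.48, limma adjusted p = 1.5e-04) but is not among the 10, because estradiol 1 at 8.79 exceeded placebo 4 at 7.43. Among the 10 largest rises, Cfd averaged 514 ± 74.7 against 49.4 ± 19.9 (log2 fold change 3.42, limma adjusted p = 8.5e-07) and Cyp2e1 80.2 ± 22.1 against 8.31 ± 2.46 (3.11, limma adjusted p = 8.9e-07). The plasma glutathione peroxidase Gpx3, the matrix protein gene Spon1, Car3, Mettl7a1, Retn, the macrophage lectin Mgl2, Adrb3 and the carboxylesterase Ces1d followed, with log2 fold changes between 1.56 and 2.26. Ces1d has close paralogs, so its value is uncertain. Emr1 averaged 2.40 ± 0.810 against 13.7 ± 12.5, Col1a1 3.64 ± 0.897 against 7.71 ± 3.01 and Mest 8.03 ± 3.48 against 22.3 ± 4.23, and all 3 fell (limma adjusted p = 7.7e-04, 0.0071 and 0.0080), Mest not after rescaling to a constant sum (log2 fold change -1.60 in place of -1.42, adjusted p = 0.177). Emr1 and Col1a1 did not pass with lane as a term, where the log2 fold changes were -1.20 in place of -1.84 and -0.36 in place of -0.85 (limma adjusted p = 0.0586 and 0.344), with standard errors of 0.39 in place of 0.34 and 0.22 in both fits, and Col1a1 passed neither within lane 6 nor as deposited (limma adjusted p = 0.339 and 0.0821). Over all alternatives the adjusted p of Emr1 ran up to 0.0586 and that of Col1a1 up to 0.344. Without placebo 3 the log2 fold change of Emr1 was -1.43.

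Of 17 lipid-associated macrophage genes 16 fell, and 16 adjusted over the list alone. The list median was -1.71, with camera adjusted p = 1.3e-12 and adjusted p = 0.180 with an estimated correlation. Estradiol 1 stood above the other estradiol libraries in several of these genes, and the list passed without any 1 library, with medians from -1.84 to -1.61. Of 21 macrophage genes 15 fell and 2 rose, with the same counts adjusted over the list alone. Their median was -1.16, with camera adjusted p = 8.4e-06 and adjusted p = 0.615 with an estimated correlation. The 2 that rose were Cd163, a haemoglobin scavenger receptor, and Lyve1, both known from tissue-resident macrophages and named after their values were seen; their log2 fold changes were 0.61 and 0.54. All 7 MHC class II genes, with the same uncertainty, fell, and 7 adjusted over the list alone. The median was -1.26, with camera adjusted p = 9.6e-07 and adjusted p = 0.309 with an estimated correlation. Of 10 cytokine and chemokine genes 6 fell, and 6 adjusted over the list alone (median -0.65, camera adjusted p = 0.0014, and adjusted p = 0.309 with an estimated correlation), among them Ccl2 at 0.539 ± 0.357 against 4.21 ± 1.47. Of 29 matrix and fibrosis genes 15 fell and 2 rose, and 16 fell and 3 rose adjusted over the list alone. Their median log2 fold change was -0.46, with camera adjusted p = 0.0013 and adjusted p = 0.806 with an estimated correlation. Timp1 averaged 0.175 ± 0.0861 against 2.28 ± 0.838. The 2 that rose, named after their values were seen, were Col14a1 and Thbs2, which encode a collagen and a thrombospondin. Of 13 histone genes 9 fell, and 9 adjusted over the list alone. The list median was -0.62, and -0.40 without placebo 2, with camera adjusted p = 8.4e-06 and adjusted p = 0.309 with an estimated correlation. Of 18 genes of the unfolded protein response 9 fell and 1, the asparagine synthetase Asns, rose, and 11 fell and 2 rose adjusted over the list alone; Asns stood at 0.88 and did not pass within lane 6 (0.75, adjusted p = 0.0647) or as deposited (0.58, adjusted p = 0.621). Their median was -0.24, with camera adjusted p = 0.0049 and adjusted p = 0.372 with an estimated correlation. The stress transcription factor Atf3 averaged 0.438 ± 0.337 against 3.63 ± 0.994.

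Of 18 branched chain amino acid genes 17 rose, and 18 adjusted over the list alone. The median was 0.55, with camera adjusted p = 2.7e-08 and adjusted p = 0.372 with an estimated correlation. Of 24 mature adipocyte genes 13 rose and 2 fell, and 15 rose and 2 fell adjusted over the list alone. Their median log2 fold change was 0.55, with camera adjusted p = 2.0e-04 and adjusted p = 0.650 with an estimated correlation. The 2 that fell were Lep, at 26.4 ± 6.86 against 53.0 ± 7.67 (log2 fold change -1.01, limma adjusted p = 0.0014), and Gpd1, a glycerol phosphate dehydrogenase. Adipoq averaged 161 ± 19.4 against 80 ± 21.5 (log2 fold change 1.03, limma adjusted p = 2.3e-04). It did not pass within lane 6 (0.71, limma adjusted p = 0.0624) or with FPKM as deposited. Of 19 insulin and glucose handling genes 12 rose and 3 fell, and 12 rose and 4 fell adjusted over the list alone. The list median was 0.41, with camera adjusted p = 0.0012 and adjusted p = 0.180 with an estimated correlation. Irs1 averaged 3.86 ± 1.04 against 0.687 ± 0.107 (log2 fold change 1.5, limma adjusted p = 8.9e-07). The 3 that fell, named after their values were seen, were Akt1, Ptpn1 and the receptor adaptor Grb14. Of 18 lipogenesis genes 7 rose, and 7 adjusted over the list alone. Their median was 0.42, with camera adjusted p = 0.0153 and adjusted p = 0.927 with an estimated correlation. Fasn averaged 29.6 ± 12.2 against 17.4 ± 4.12 and did not pass (log2 fold change 0.69, limma adjusted p = 0.106). Scd1 averaged 639 ± 70.6 against 371 ± 98.4 (log2 fold change 0.82, limma adjusted p = 0.0055), and was not called with lane as a term or within lane 6 (0.62 and 0.61, adjusted p = 0.141 and 0.0937), with quantile normalization (0.24, adjusted p = 0.515), as deposited (0.48, adjusted p = 0.779) or rescaled to a constant sum (0.77, adjusted p = 0.0570). With lane as a term the standard error of Scd1 was 0.26 in place of 0.20. Of 40 oxidative phosphorylation genes 3 rose, and 0 adjusted over the list alone (median 0.19, camera adjusted p = 0.0125, and adjusted p = 0.927 with an estimated correlation); the list was lost without placebo 1, 2 or 5 or without estradiol 3, with adjusted p up to 0.122. Its median was 0.11 without placebo 1, and as deposited it was -0.14. The tricarboxylic acid cycle, steroid metabolism and ribosomal protein lists, which passed with diet, did not pass camera or fry here. Of 22 tricarboxylic acid cycle genes 2 rose, and 1 adjusted over the list alone. Of 8 steroid genes 2 rose and 1 fell, with the same counts adjusted over the list alone, and of 39 ribosomal protein genes 0 passed limma or passed adjusted over the list alone (camera adjusted p = 0.0985, 0.649 and 0.578).

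By limma, 1706 of 5615 genes differed, 805 higher and 901 lower with estradiol; 196 changed by more than 1 on the log2 scale, 50 up and 146 down. Groups did not overlap in 1193 of the 5615 genes, against 0.794% by chance. Of the called genes 47.2% were higher. Over the same 5615 genes it was 4.71% of 276 with FPKM as deposited and 33.0% of 748 after rescaling to a constant sum. The median of all tested genes then lay at -0.27 and -0.045. Within lane 6, with 5 estradiol and 2 placebo libraries, 637 of 6355 genes differed, and with lane as a term 711 of 5615. The lipid-associated macrophage median was -1.30 and -1.29, and that of branched chain amino acid catabolism 0.41 and 0.39. Within lane 6 the factors and tested genes were set anew from its libraries, so its scale and genes differ from those of the full fit. With lane as a term the matrix, lipogenesis and oxidative phosphorylation lists no longer passed (adjusted p = 0.0605, 0.0780 and 0.592), and within lane 6 the lipogenesis, oxidative phosphorylation and histone lists (adjusted p = 0.0719, 0.644 and 0.0519).

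**Figure D2:**
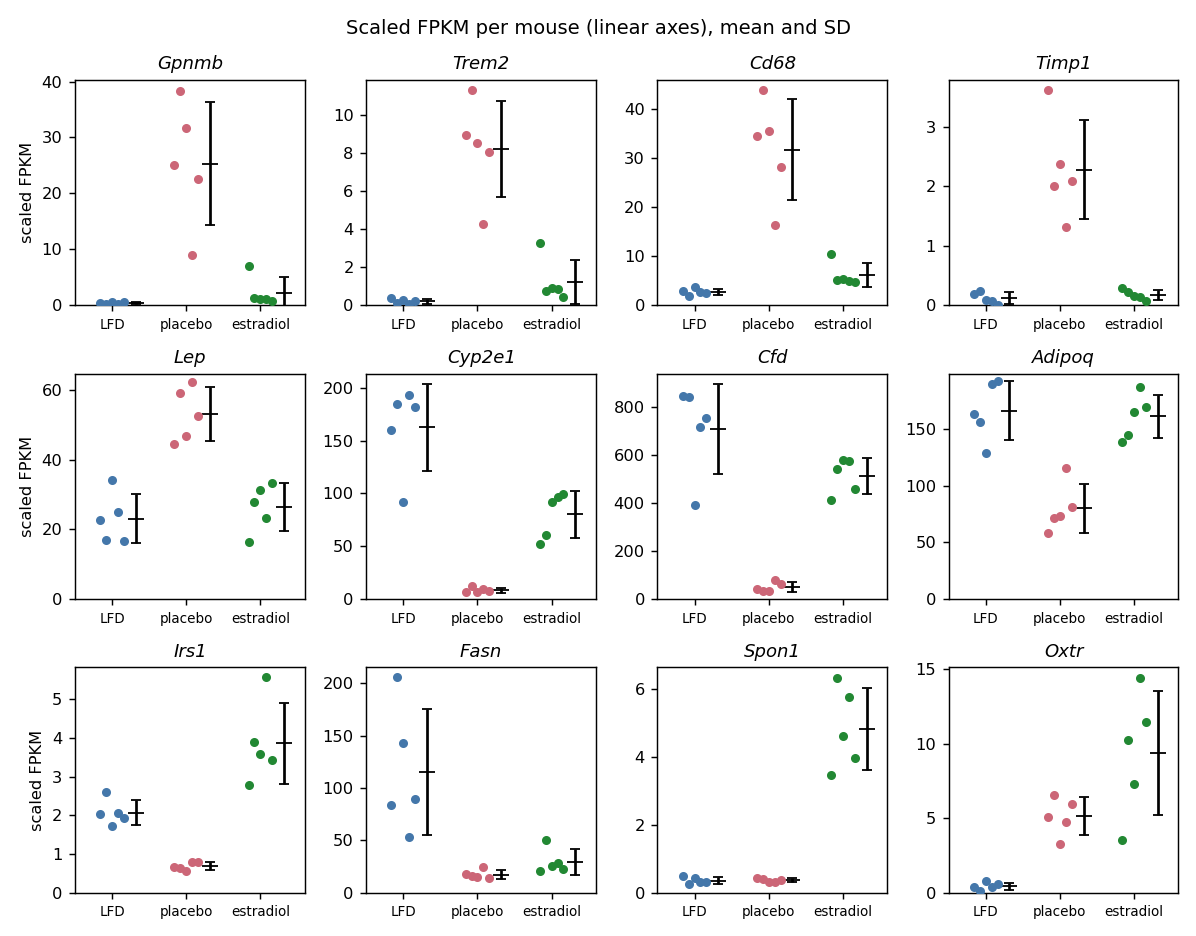
Scaled FPKM of 12 genes in each mouse on linear axes, 5 points per group in blue for LFD, red for HFD placebo and green for HFD estradiol, with the mean as a horizontal tick and the SD as a bar, whose lower end is not drawn below 0. Gpnmb averaged 0.432, 25.3 and 2.26 in the 3 groups in that order, Cfd 711, 49.4 and 514, and Spon1 0.359, 0.375 and 4.83; Adipoq averaged 166, 80 and 161, and its fall with diet is a rise of 0.077 on the log2 scale with FPKM as deposited.

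The third comparison sets HFD estradiol against LFD, where diet, pellet and lane all differ. Lipogenic genes were among the largest falls. Fasn averaged 29.6 ± 12.2 with estradiol and 115 ± 60.2 in LFD (log2 fold change -1.85, limma adjusted p = 0.0018), and Acacb, an acetyl-CoA carboxylase, 0.838 ± 0.229 against 4.48 ± 2.23 (-1.51, limma adjusted p = 1.4e-04). Thrsp, Acss2, Acaca, Me1, Gpd1, the acyl-CoA synthetase Acsm3, the apolipoprotein gene Apoc1 and the complement gene C7 completed the 10 largest falls, between -1.74 and -1.28. Among the 10 largest rises, Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112489943), averaged 9.40 ± 4.15 against 0.451 ± 0.232 (log2 fold change 2.74, limma adjusted p = 1.0e-05), and Spon1 (chromosome 7, 113765998 to 114043370) 4.83 ± 1.21 against 0.359 ± 0.0924 (2.08, limma adjusted p = 1.5e-08). Thbs1, Lum, the growth factor Gas6, the interleukin 4 receptor Il4ra, the complement gene C4b, the transglutaminase Tgm2, Sncg and Gpx3 followed, between 2.34 and 1.32. Lep averaged 26.4 ± 6.86 against 23.1 ± 7.10, Adipoq 161 ± 19.4 against 166 ± 25.9 and Ccl2 0.539 ± 0.357 against 0.543 ± 0.459, and none of the 3 passed (limma adjusted p = 0.632, 0.915 and 0.980). Nor did Trem2, Col1a1 or Emr1 (limma adjusted p = 0.0742, 0.436 and 0.520). Trem2 still ran higher, from 0.411 to 3.25 with estradiol and from 0.0596 to 0.389 in LFD, without overlap. Col1a1 and Emr1 overlapped between the groups. Mest and Mmp12 stayed higher than in LFD, with log2 fold changes of 1.41 and 1.29 (limma adjusted p = 0.0291 and 0.0480). Mmp12 stood at 8.79 in estradiol 1, far above the other estradiol libraries. With lane as a term neither passed, at 1.03 and 1.92 (limma adjusted p = 0.405 and 0.126).

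Of 18 lipogenesis genes 11 fell, and 16 adjusted over the list alone. The median was -1.09, with camera adjusted p = 8.6e-14 and adjusted p = 0.476 with an estimated correlation. Of 14 cholesterol synthesis and uptake genes 3 fell, and 9 adjusted over the list alone. The median stood at -0.43, with camera adjusted p = 5.1e-05 and adjusted p = 0.644 with an estimated correlation. Of 22 tricarboxylic acid cycle genes 3 fell, and 4 adjusted over the list alone (median -0.34, camera adjusted p = 8.8e-06; without LFD 2 the median was -0.18, with adjusted p = 8.7e-04). Of 18 branched chain amino acid genes 3 fell, and 6 adjusted over the list alone (median -0.28, camera adjusted p = 1.5e-04), and of 24 mature adipocyte genes 5 fell, and 7 adjusted over the list alone (median -0.23, camera adjusted p = 5.1e-04); for these 3 lists adjusted p = 0.644 with an estimated correlation. Of 29 matrix and fibrosis genes 9 rose, and 13 adjusted over the list alone. The median stood at 0.31, with camera adjusted p = 7.6e-09 and adjusted p = 0.638 with an estimated correlation. Thbs1 averaged 12.5 ± 7.26 against 1.43 ± 0.466, Thbs2 3.17 ± 0.645 against 0.621 ± 0.170 and Lum, which encodes the collagen-binding lumican, 7.33 ± 2.85 against 1.09 ± 0.327. Of 21 macrophage genes 8 rose, and 11 adjusted over the list alone. Their median was 0.42, with camera adjusted p = 2.4e-06 and adjusted p = 0.644 with an estimated correlation. The mannose receptor Mrc1 averaged 6.43 ± 1.5 against 3.32 ± 0.550 and the lectin Clec10a 5.00 ± 1.53 against 1.84 ± 0.485. Of 12 adipose progenitor genes 4 rose, and 6 adjusted over the list alone (median 0.30, camera adjusted p = 1.5e-04, and adjusted p = 0.476 with an estimated correlation), among them Pdgfra at 2.69 ± 0.731 against 1.42 ± 0.209. Of 39 ribosomal protein genes 2 rose, and 2 adjusted over the list alone. The median was 0.17, with camera adjusted p = 2.4e-06 and adjusted p = 0.644 with an estimated correlation.

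Another 4 lists passed camera only narrowly. Of 8 steroid genes 2 fell, and 3 adjusted over the list alone (median -0.22, camera adjusted p = 0.0334, and adjusted p = 0.476 with an estimated correlation); the 2 were Hsd11b1, which regenerates active glucocorticoid, and Sult1e1, an estrogen sulfotransferase. Of 40 oxidative phosphorylation genes 0 passed at an adjusted p below 0.05 by limma or adjusted over the list alone. The median stood at -0.17, with camera adjusted p = 0.0193 and adjusted p = 0.841 with an estimated correlation. Both lists were lost without LFD 2, estradiol 1 or estradiol 5, with adjusted p up to 0.0823 and 0.663, and the oxidative phosphorylation median was -0.047 without LFD 2 and -0.11 without estradiol 1. Of 17 lipid-associated macrophage genes 1 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone. The median stood at 0.34, with camera adjusted p = 0.0248 and adjusted p = 0.684 with an estimated correlation. This list was lost without LFD 2 or estradiol 1, with adjusted p up to 0.109, and its median was 0.18 without estradiol 1. Of 10 cytokine and chemokine genes 4 rose, and 4 adjusted over the list alone (median 0.31, camera adjusted p = 0.0248, and adjusted p = 0.644 with an estimated correlation), and the list was lost without LFD 2, estradiol 1 or any 1 placebo library, with adjusted p up to 0.145.

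By limma, 432 of 5615 genes differed, 222 higher and 210 lower with estradiol; 50 changed by more than 1 on the log2 scale, 26 up and 24 down. Groups did not overlap in 452 of all 5615 tested genes, against 0.794% by chance. Of the called genes 51.4% were higher. Over the same genes it was all 39 with FPKM as deposited and 95.5% of 643 after rescaling to a constant sum. The median of all tested genes then lay at 0.49 and 0.38. As deposited, the medians of the adipocyte, oxidative phosphorylation, tricarboxylic acid, branched chain amino acid and steroid lists were 0.53, 0.55, 0.36, 0.40 and 0.38. After rescaling they were 0.16, 0.21, 0.030, 0.056 and 0.11. That of cholesterol synthesis was 0.046 as deposited. No lane holds both groups, so no value within a lane can be had, and with lane as a term, which the placebo libraries alone inform, 162 genes differed, 105 of them among the 432. With that term Fasn, Thrsp, Acss2, Acaca, Me1, C4b, Tgm2, Sult1e1 and Clec10a did not pass (limma adjusted p from 0.0507 for Thrsp to 0.135 for Sult1e1). Their log2 fold changes were -2.01 in place of -1.85 for Fasn, -1.92 in place of -1.74 for Thrsp, -1.92 in place of -1.72 for Acss2, -1.71 in place of -1.42 for Acaca, -1.39 in place of -1.28 for Me1, 1.41 in place of 1.37 for Tgm2 and 1.09 in place of 1.06 for Clec10a. For C4b, at 1.21 in place of 1.42, and Sult1e1, at -0.96 in place of -1.23, they were smaller. The standard errors of the 9 rose from between 0.19 and 0.31 to between 0.34 and 0.56, so for the 7 whose fold changes were not smaller the calls ended through lower precision. Leaving out LFD 4, LFD 5 and estradiol 3, which held muscle or prostate transcripts, left 170 calls and ended that of Pdgfra, whose log2 fold change was 0.59 in both fits, and leaving out the 4 libraries with the most Ucp1, LFD 2, placebo 3, placebo 4 and estradiol 3, left 274.

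**Figure D3:**
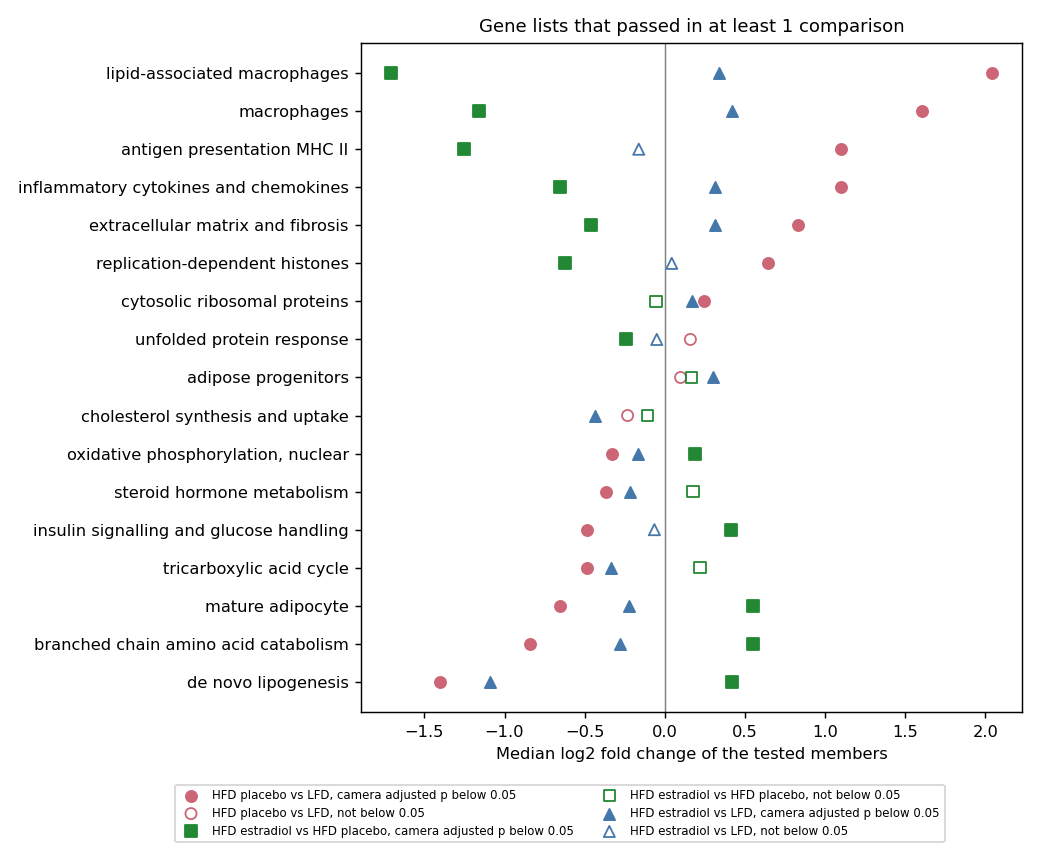
Median log2 fold change of the tested members of the 17 gene lists that passed camera in at least 1 comparison, with circles for HFD placebo against LFD, squares for HFD estradiol against HFD placebo and triangles for HFD estradiol against LFD, filled where the camera adjusted p was below 0.05. Lipid-associated macrophages stood at 2.04, -1.71 and 0.34 and de novo lipogenesis at -1.40, 0.42 and -1.09; with FPKM as deposited the medians below 0 are positive for mature adipocyte (0.49 and 0.53), tricarboxylic acid cycle (0.54 and 0.36), oxidative phosphorylation (0.71 and 0.55), branched chain amino acid catabolism (0.091 and 0.40) and steroid metabolism (0.40 and 0.38) in both comparisons with LFD, and for insulin handling with placebo (0.28) and cholesterol synthesis with estradiol (0.046) against LFD, while oxidative phosphorylation with estradiol against placebo falls to -0.14.

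The comparisons were then joined to ask where estradiol moved the genes that differed with diet. Of the 2431 genes that differed between HFD placebo and LFD, 2311, or 95.1%, changed in the opposite direction between HFD estradiol and HFD placebo. Both comparisons use the same placebo libraries. Groups simulated with no effect gave a median of 76.5% and at most 93.6% in 100 runs, over the 2431 genes of smallest p in each run. Those genes carried no diet difference, so 76.5% is not the share that shared libraries alone would give the called genes. With the placebo libraries split between the comparisons in 20 ways, the share had a median of 93.6% and ran from 85.5% to 96.0%; with lane as a term it was 87.5%. The covariance of the 2 sets of log2 fold changes across genes was -0.170 against -0.0078 simulated, a difference of -0.162, and -0.161 at the median of the splits. Of the 2431 genes 1431, or 58.9%, also passed in the opposite direction with estradiol, and 16 passed in the same direction. The number up with diet and down with estradiol was 782, and the number down and then up was 649. Of the 2431 genes 336, or 13.8%, still differed between HFD estradiol and LFD, 316 of them in the direction of the diet difference. Gpnmb and Cd68 lay among the genes that rose with diet and fell with estradiol, Cfd and Cyp2e1 among those that fell and then rose. With estradiol Gpnmb ran from 0.668 to 7.09 and Cd68 from 4.80 to 10.3. Both stayed above all LFD libraries, which reached at most 0.627 and 3.75. Cfd ran from 414 to 580 with estradiol and from 391 to 847 in LFD. Cyp2e1 ran from 51.9 to 99.2 with estradiol and from 92.2 to 193 in LFD. Fasn, Thrsp and Acaca were lower than LFD in both high-fat groups.

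**Figure D4:**
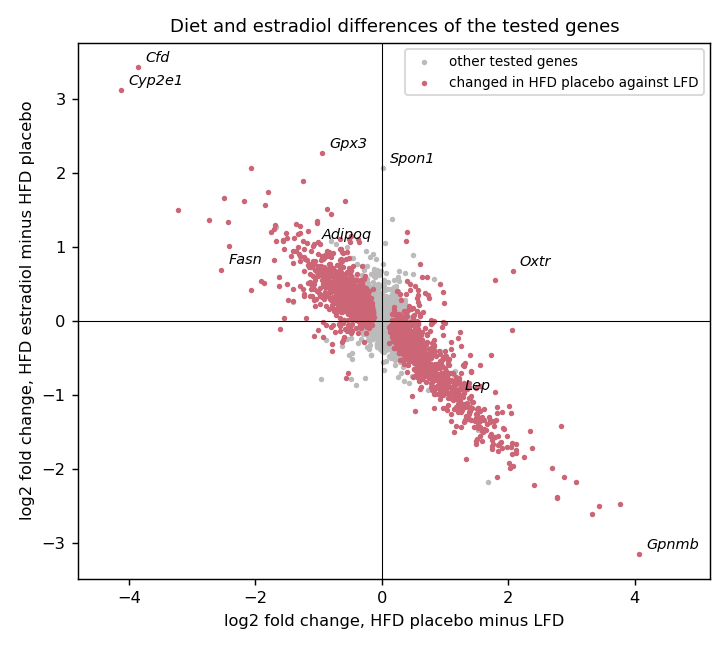
Log2 fold change of each of the 5615 tested genes in HFD placebo minus LFD on the horizontal axis and in HFD estradiol minus HFD placebo on the vertical axis, with red for the 2431 genes that differed in the first comparison and grey for the others. Of the red genes 95.1% lie in the quadrants of opposite sign. Groups simulated with no effect gave a median of 76.5% over the 2431 genes of smallest p in each run, which carried no diet difference. Adipoq, at -1.07 on the horizontal axis, stands at 0.077 with FPKM as deposited.

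Genes of estrogen signalling were looked at by name, and Esr1, Pgr and Greb1 lay below the level tested by limma. Esr1, the estrogen receptor alpha gene (chromosome 10, 4611593 to 5005614), averaged 0.712 ± 0.156 in LFD, 0.239 ± 0.0844 in HFD placebo and 0.639 ± 0.121 in HFD estradiol. In an exact two-sided permutation test placebo lay below LFD and below estradiol (p = 0.0079 each, adjusted 0.0190 over 24 tests), the smallest value that 5 against 5 mice allow, and the difference between estradiol and LFD did not pass (p = 0.452). These Esr1 results depend on the scaling. With FPKM rescaled to a constant sum placebo lay below both groups with the same p, but as deposited Esr1 averaged 0.451 in LFD, 0.427 in placebo and 0.763 in estradiol, with exact permutation p = 0.865 for placebo against LFD and 0.127 for estradiol against placebo. Pgr, the progesterone receptor gene and a known estrogen target, averaged 0.0604 ± 0.0209 with estradiol and 0.0033 ± 0.0040 with placebo, and was above 0 in 1 of 5 LFD, 3 of 5 placebo and 5 of 5 estradiol libraries (exact permutation p = 0.0079 for estradiol against either group). Greb1, also a known estrogen target, averaged 0.0340 ± 0.0202 with estradiol and 0.0014 ± 0.0021 with placebo (exact permutation p = 0.0079, and 0.0159 against LFD). The differences of Pgr and Greb1 passed as deposited and rescaled as well (largest adjusted p = 0.0476). Both Pgr and Greb1 lay far below the lowest level tested by limma, a scaled FPKM of 1. The aromatase gene Cyp19a1 and the seminal vesicle gene Svs4 were listed at 0 in all 15 libraries, and the prostate gene Pbsn reached 0.314 in estradiol 5. The list of 9 tested estrogen receptor targets did not pass camera in any comparison (adjusted p = 0.466, 0.700 and 0.496); with diet 2 rose and 5 fell, and 3 and 6 adjusted over the list alone, and with estradiol against placebo 3 rose and 3 fell, and 5 and 3 adjusted over the list alone. Against LFD with estradiol 1 of the 9, Sult1e1, fell, and 1 rose and 2 fell adjusted over the list alone.

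The tested lists in this paragraph did not pass camera in any comparison. Fry, which does not compare a list with other genes, called secreted adipokines (adjusted p = 4.7e-05 with diet and 0.0030 with estradiol against placebo), immediate early genes (0.0061 and 0.0070), and with diet Schwann cells, B and plasma cells and the circadian clock (0.0045, 0.0250 and 0.0464). Ucp1, the uncoupling protein of brown fat, varied between mice from 0 to 34.2 and averaged 8.33 ± 14.5 in LFD, 8.07 ± 11.9 in HFD placebo and 1.46 ± 2.09 in HFD estradiol, and 0 of 5 brown and beige fat genes passed limma in any comparison or adjusted over the list alone (camera adjusted p = 0.562, 0.784 and 0.200). Secreted adipokine genes went both ways with diet, 6 of 16 up and 7 down, and with estradiol against placebo, 7 up and 5 down (camera adjusted p = 0.562 and 0.671); adjusted over the list alone these were 6 and 7, and 7 and 6. With estradiol against placebo their median was -0.11 and their mean 0.092. Fatty acid oxidation genes fell in 7 of 23 cases and rose in 1 with diet, 4 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0819). The 10 tested interferon response genes gave 2 rises with diet, 1 adjusted over the list alone, and none in the other comparisons (camera adjusted p = 0.384, 0.578 and 0.587). The smallest camera adjusted p over the 3 comparisons was 0.0527 for fat pad expansion, 0.0592 for immediate early genes, 0.108 for B and plasma cells, 0.190 for the circadian clock, 0.200 for smooth muscle and 0.299 for endothelium. It was 0.398 for Schwann cells, 0.423 for neutrophils, 0.449 for complement, 0.465 for mesothelium, 0.579 for hypoxia and 0.879 for erythroid genes. Another 9 lists had fewer than 3 tested members and were not tested as lists. Of the proliferation list, Mki67 rose with diet and fell with estradiol against placebo, with log2 fold changes of 1.05 and -1.13, as did Pcna, with 0.96 and -1.0; both were named after their values were seen.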

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

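The lane tests and the counts over other splits of the samples were laid down before their results were seen, though after the counts with lane as a term, while the endothelium, prostate and mislabelling tests and the lowest level of 0.3 used below were chosen after the result was seen. A value is given here when 1 library lay so far from the other 4 of its group that the gap exceeded 0.71 of the range of the group. Of 436 groups of 5 values tested 55 met this, where chance alone would give about 21.8, so single entries carry little weight. Values are scaled FPKM.

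Estradiol 1 lay above the other estradiol libraries in 12 genes, most of them of macrophages. They were Gpnmb at 7.09, where the others ran from 0.668 to 1.34, Mmp12 at 8.79, Lgals3 at 13.1, Cd68 at 10.3, Trem2 at 3.25, Ctss at 19.9, Atp6v0d2 at 1.70, Lipa at 6.05, Ccl9 at 4.31, Adam8 at 1.58, Mpeg1 at 3.30 and Atf3 at 1.03. It lay below them in Hsd17b12 at 4.57 and Dbt at 1.36. LFD 2 lay above the other LFD libraries in Aacs at 9.93, Cox6c at 51.1, Ndufb9 at 38.5, Sdha at 23.5, Pdhb at 16.7, Slc2a4 at 8.13, Mlxipl at 4.28, Atp5c1 at 20.5, Acacb at 8.43 and Hsd17b12 at 12.1. Its Ucp1 stood at 34.2, with the others from 0.960 to 2.47, and its brown and beige fat list score, the mean log2 value of the members, at 1.65. It lay below the other LFD libraries in C1qb at 4.78, Cd34 at 5.24 and Rpl27 at 1.65. Placebo 4 lay above its group in Cox8a at 35.3, Cox6c at 23.8, Aldh6a1 at 8.68, Ivd at 3.19, Slc2a4 at 2.55 and Atp5c1 at 15.0, and below it in Atf3 at 1.90, Anxa3 at 2.76 and Ctsk at 2.35. Ucp1 was also high in placebo 4 at 26.6, in placebo 3 at 13.5 and in estradiol 3 at 4.96.

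The remaining entries were spread over 9 libraries. LFD 1 was high in C7 at 6.34 and Sult1e1 at 6.00 and low in Fdft1 at 1.35. LFD 3 was low in Cfd at 391 and Mettl7a1 at 8.12 and high in Hsd11b1 at 8.94. Placebo 1 was high in Hsd17b11 at 1.68 and in the erythroid list score at 2.81, and placebo 3 in Emr1 at 35.9, with the others from 5.58 to 9.72. Estradiol 2 was high in Fasn at 50.7 and low in Postn at 4.46. Estradiol 3 was high in the skeletal muscle list score at 0.972, estradiol 4 in Suclg2 at 1.21 and Hist1h1a at 0.508, and estradiol 5 in Ubd at 3.28 and Pbsn at 0.314. LFD 5 was high in the prostate and seminal vesicle list score at 1.5, with the others from 0.0717 to 0.105.

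The placebo libraries lay apart from both other groups in macrophage genes. The sequencing lane as the whole cause is argued against by the values within lanes, since the lipid-associated macrophage median was 1.40 for placebo against LFD within lane 5 and -1.30 for estradiol against placebo within lane 6. The 1.40 leaves out members near 0 in LFD, such as Gpnmb and Trem2, which the filter dropped within lane 5. A loss of adipocytes that raised every other cell type alike is argued against by the endothelium list. Its median was -0.074 with quartiles of -0.15 and -0.0056, where the macrophage median was 1.61 with quartiles of 0.97 and 2.05. Shuffling genes between these lists, which share Lyve1, gave permutation p = 4.9e-04 over 100000 resamples. That p treats genes of the same mice as independent, so it does not measure the spread between mice. The adipose progenitor and smooth muscle medians stood at 0.099 and 0.22. As deposited the endothelium stood at 0.68, below the shift of 0.77 of the median gene. In 100 splits of the 10 libraries, the real one gave the most genes. It gave 2431 against at most 1418 in another for placebo against LFD, and 1706 against at most 1207 for estradiol against placebo. So 1 of 100 was as large in each, the smallest share that 100 splits can give. This makes chance an unlikely cause but does not exclude it. More macrophages or a changed macrophage state in obese fat, both tied to the diet and pellet groups, may explain the pattern, and these data do not separate them.

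The estradiol libraries differed from LFD in 432 genes although all of one group lay on lane 6 and all of the other on lane 5. Only the placebo group spans both lanes. Over the 222 genes higher with estradiol, whose median difference from LFD was 0.54, the lane 6 minus lane 5 difference among placebo libraries had a median of -0.062, and over the 210 lower genes, with a median of -0.48, it was 0.099, with the same sign in 33.8% and 27.1% of genes. The placebo libraries thus showed no lane difference in the direction of the estradiol difference for these genes as a set. This contrast of 3 against 2 placebo libraries also mixes lane with differences between mice. Placebo 4, on lane 6, had a median position of 0.592 between the LFD mean at 0 and the placebo mean at 1. The other placebo libraries ran from 0.963 to 1.13. The contrast therefore does not decide about lane, for the set or for single genes. Limma called lane itself in 0 genes, a test with little power on so few libraries. Of 5615 genes 515 had an unadjusted limma p under 0.05, a larger share than chance gives on average. Genes of the same libraries move together, so chance can also give larger shares, and whether this one exceeds chance was not tested. Of 100 splits 1, the real one, gave as many genes, with at most 10 in another. This makes chance an unlikely cause but does not exclude it. The real split is also the split by lane, so the count does not bear on lane. Diet, estradiol and pellet placement remain as untested biological candidates that may act together.

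LFD 5 was high in transcripts of the prostate and seminal vesicle list. Of the 25 members of the prostate and seminal vesicle list 11 were highest in LFD 5 at 5 times the next library or more, against at most 1 in any other library; the abundant members Sbp, Spink3 and Sbpl stood at 576, 125 and 26.8. Not every member was present, since Pbsn and Svs4 stood at 0 in LFD 5 and Pbsn was highest in estradiol 5 at 0.314. An exchange of LFD 5 with a library of another group is argued against by its place between the group means, over the genes called without it. On a scale from 0 for the mean of the other LFD libraries to 1 for the estradiol mean its median was 0.075, where the other LFD libraries, each placed in this way without itself, ran from -0.19 to 0.28 and the estradiol libraries from 0.76 to 1.07. On the scale to the placebo mean it was 0.0068, with the other LFD libraries from -0.17 to 0.20 and the placebo libraries from 0.59 to 1.13. A small amount of prostate tissue in the dissected fat may explain these transcripts. Of the 25 members 1, Mme, reached the tested level across the fat libraries, and no biological explanation was tested.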

How the results depend on the processing

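The fits within lanes and without chosen libraries, the scalings of the exact tests of Cd79a, Cd79b, Top2a and Il7r and the alternatives for genes that differed from both groups were added after the data were seen, and the other alternatives were fixed before the data were examined. Where no reason is given below, the cause was not tested. Of 210 gene values named with a limma test 187 were called; 164 of these kept their direction under every alternative run for them and 85 also stayed past the threshold.

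Counts of called genes moved by more than 1.5 times under some alternatives. With FPKM as deposited, estradiol against placebo gave 295 calls and estradiol against LFD 42, and the share of diet-changed genes with the opposite sign was 98.0%. Here the filter was applied to the values as deposited, so the tested genes differed. Over the 5615 genes of the main fit the calls as deposited were 276 and 39. Rescaled to a constant sum per library, estradiol against placebo gave 748. With no filter, 18880 genes were tested and 3908 and 2606 were called in the first 2 comparisons. With a mean of at least 5, only 942 genes were tested and 524, 382 and 140 were called, fewer because fewer were tested. With lane as a term, estradiol against placebo gave 711, of which 692 were shared with the 1706, estradiol against LFD gave 162, with 105 shared, and the share of opposite sign was 87.5%. Within lane 5 placebo against LFD gave 1343 calls, 1267 shared, and within lane 6 estradiol against placebo gave 637, 567 shared. Both had fewer libraries, with factors and tested genes set anew. Without the 4 libraries with most Ucp1, estradiol against LFD gave 274, and without the 3 libraries with prostate or muscle transcripts 170. With the placebo libraries split between the comparisons the share of opposite sign had a median of 93.6%.

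The list tests rest on the preset correlation: with a correlation estimated from the data, the lists called were 0, 0 and 0 in the 3 comparisons in place of 14, 12 and 13. Fry gave 21, 14 and 4. With lane as a term they were 15, 9 and 16.

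Leaving out each library in turn gave 2019 to 2478 calls for placebo against LFD, 1308 to 1853 for estradiol against placebo and 297 to 508 for estradiol against LFD, with 13 to 16, 11 to 14 and 9 to 15 lists, and a share of opposite sign from 94.1% to 95.9%, the highest without placebo 4. Of the called gene values under these exclusions 2613 stayed past the threshold and 122 did not. The replicate number as a block, which pairs different animals, gave 2427, 1685 and 431 calls and 14, 12 and 12 lists, and a share of 94.9%; only 5 of 15 libraries correlated best with a library of their own number.

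Directions turned mostly with the scaling, because FPKM as deposited shifts the median gene by 0.77 for placebo against LFD (0.23 in its lane 5 and 1.59 in its lane 6 libraries) and by 0.49 for estradiol against LFD. As deposited, the log2 fold changes of placebo against LFD that were negative became 0.037 for Hsd11b1, 0.25 for Hsd17b10, 0.38 for Hsd3b7, 0.42 for Hsd17b11, 0.53 for Cox8a, 0.43 for Cox6c, 0.36 for Ndufb9, 0.35 for Sdha, 0.045 for Pcx, 0.16 for Suclg2, 0.081 for Mpc1, 0.27 for Insr, 0.031 for Gys1, 0.077 for Adipoq and 0.54 for Ucp1. Those of estradiol against LFD became 0.30 for Hsd17b12, 0.38 for Hsd17b10, 0.19 for Lpl, 0.18 for Slc2a4, 0.046 for Fdft1, 0.0087 for Idi1, 0.41 for Ndufa8, 0.39 for Ndufb8, 0.45 for Sdhc, 0.35 for Uqcrfs1, 0.13 for Pcx, 0.18 for Mpc2, 0.15 for Pdhb, 0.097 for Mccc1, 0.15 for Dbt, 0.28 for Aldh6a1, 0.014 for Fabp5 and 0.77 for Adipoq. Rescaled to a constant sum, estradiol against LFD became 0.032 for Hsd17b10, 0.071 for Ndufa8, 0.0022 for Ndufb8, 0.098 for Sdhc, 0.011 for Uqcrfs1 and 0.36 for Adipoq. A further 70 called values were no longer past the threshold as deposited, 31 rescaled to a constant sum and 36 with lane as a term.

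The other reversals were in values not called. For estradiol against LFD, quantile normalization gave 0.14 for Adipoq and -0.12 for Ccl2, array weights -0.054 for Ccl2, lane as a term -0.0036 for Lep, the fit without the 4 libraries with most Ucp1 -0.092 for Ccl2, and the fit without the 3 libraries with prostate or muscle transcripts 0.091 for Adipoq. Array weights gave 0.12 for Ucp1 in estradiol against placebo. Leaving out 1 library, Ucp1 in placebo against LFD ran from -1.10 without placebo 4 to 0.31 without LFD 2, and was also positive, 0.047 and 0.022, without placebo 1 or 2. In estradiol against LFD, Ccl2 ran from -0.11 without estradiol 4 to 0.17 without LFD 4, and was also negative, -0.087 and -0.066, without LFD 2 or LFD 5. Adipoq ran from -0.12 without LFD 3 to 0.018 without LFD 5, and was also positive, 0.012 and 0.013, without LFD 4 or estradiol 1. The exact tests were repeated only with FPKM as deposited and rescaled to a constant sum. As deposited, the difference of means changed sign to 0.311 for Esr1, 0.280 for Cd79b and 0.0436 for Top2a in estradiol against LFD, to 0.0023 for Greb1 and 0.290 for Cd79b in placebo against LFD, and to -0.0671 for Cd79a and -0.0102 for Cd79b in estradiol against placebo. Rescaled, it changed sign to 2.54 for Esr1 and 0.196 for Top2a in estradiol against LFD. None of these differences passed. Depth limits the low genes most, since the estimated fragments at the lowest tested level start at 20.7 in LFD.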

Other observations

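The values here were looked at after the comparisons were seen. By limma 74 genes were higher and 18 lower with estradiol than in both other groups. Independent lists would share 31.8 and 33.7, though both comparisons use the same estradiol libraries. With different estradiol libraries in each comparison, 2 in one and 3 in the other, the first number had a median of 29.5 over 20 ways and ran from 18 to 35, where independent lists of the same sizes would share 7.56, and the second had a median of 4 and ran from 1 to 7, against 9.19. The genes higher than both were thus more, and those lower than both fewer, than independent lists would share with the factors used. The numbers depend on the processing: they were 4 and 0 by limma with FPKM as deposited, 51 and 5 rescaled to a constant sum, 85 and 22 with quantile normalization and 19 and 5 with lane as a term. Of the 74, 44 did not differ between placebo and LFD, and of the 18, 12 did not. Spon1 had log2 fold changes of 2.06 against placebo and 2.08 against LFD, Gas6 1.37 and 1.54, Il4ra 1.07 and 1.46, Mgl2 1.62 and 1.03, Plod2 1.2 and 1.60, and Igfbp4 1.06 and 0.69. Sult1e1 stood at -0.71 and -1.23, C7 at -0.77 and -1.34 and Gpd1 at -0.79 and -1.28.

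The B cell gene Cd79a, chosen after its values were seen, averaged 1.53 ± 0.327 in LFD, 0.477 ± 0.343 in placebo and 0.706 ± 0.359 in estradiol libraries, with exact two-sided permutation p = 0.0079 for placebo against LFD, 0.0159 for estradiol against LFD and 0.325 for estradiol against placebo. Neither difference from LFD was kept as deposited (exact permutation p = 0.976 and 0.762) or rescaled to a constant sum (adjusted p = 0.104 and 0.278). Its partner gene Cd79b averaged 2.38 ± 1.06, 1.03 ± 0.724 and 1.42 ± 0.994. It did not pass this test, with exact permutation p = 0.0397 (adjusted 0.0733) for placebo against LFD. The exact permutation p was 0.190 for estradiol against LFD and 0.476 for estradiol against placebo. Both B cell genes also reached the level tested by limma. The cell cycle gene Top2a averaged 0.142 ± 0.0422, 0.882 ± 0.204 and 0.117 ± 0.0232, with exact permutation p = 0.0079 for placebo against either group and 0.294 for estradiol against LFD. The interleukin 7 receptor Il7r averaged 0.0909 ± 0.0458, 1.45 ± 0.421 and 0.202 ± 0.197, with exact permutation p = 0.0079 for placebo against either group and 0.198 for estradiol against LFD. For Top2a and Il7r the differences of placebo from either group passed as deposited and rescaled as well. Estrogen receptor beta, Esr2, was above 0 only in placebo 4, at 0.0027, and in estradiol 3, at 0.0092. It gave an exact permutation p of 1 in all 3 comparisons, and with so few values above 0 the test could not pass.

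Acta1, a skeletal muscle actin, stood at 6.35 in LFD 4 and 4.99 in estradiol 3. Hoxb13, a prostate transcription factor, stood at 1.07 in LFD 5.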
